A study of Mus musculus with 9 samples.

How the data were processed

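Ovarian RNA of 9 mice aged 3 weeks was profiled, with 3 mice labelled wild type, 3 labelled Taf4b heterozygote and 3 labelled Taf4b knockout, 1 array per mouse. Per the series' design text, RNA quality was checked on a Bioanalyzer and its concentration on a Nanodrop, and 300 ng of total RNA per mouse were labelled as sense-strand targets by the Affymetrix whole-transcript protocol, revision 3, for GeneChip Mouse Gene 1.0 ST arrays. The labels name Trizol for the extraction. Samples were grouped by genotype and numbered as the submitters' labels give them.

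Per the series' design text, the authors obtained the intensity values with RMA-Sketch in Affymetrix Expression Console 1.1, which corrects background, normalizes arrays to a common distribution and summarizes probes into probe sets. RMA values are commonly given as logs, but the deposited intensity values are linear, as their range shows, and log2 values were computed from them here. The authors also deposited 3 tables of pairwise comparisons with, per the file headers, group mean intensities, a ratio (fold change, wild type over knockout, wild type over heterozygote, and heterozygote over knockout) and a p-value. The intensities in those tables equal the value table. The authors' deposited p-value equals that of a two-sided equal-variance test on linear intensities in 100% of the cells that hold one, within 1e-06, and the 3 tables have 19, 29 and 21 cells without a value. In the authors' deposited tables, p is under 0.05 at 1819 probe sets for wild type against knockout, 1146 for wild type against heterozygote and 1931 for heterozygote against knockout. After Benjamini-Hochberg adjustment of the authors' p-values these become 3, 0 and 1. The fold of Taf4b, wild type over knockout, is 1.36 in the authors' deposited table, with p = 0.214. The annotation release behind the tables is not given in the sources used here, and some probe set descriptions carry coordinates of the mouse build NCBIM37.

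Of 28266 probe sets, 3166 had no gene symbol, 24948 had 1 and 151 had several. A spreadsheet had turned 26 symbols into dates, and these were replaced by the symbol in the description where it gave 1. Replaced symbols are included in the counts. Symbols were updated through the RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order alone: 18712 probe sets matched by accession, 2208 by symbol, 1751 by synonym and 2277 not at all, and these kept the symbol of the file. The 25100 probe sets with a symbol stand for 22230 genes, 1344 of them with several probe sets, and 313 probe sets repeat the values of another exactly, so counts are given of probe sets and of genes. Older symbols of named genes are those of the deposited annotation. No value column was left unmapped (0).

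Differences were tested on log2 values with limma 3.58.1 in R 4.3.3, with 1 linear model over all 9 arrays, eBayes moderation and Benjamini-Hochberg adjustment over the 25100 probe sets, two-sided, at an adjusted p of 0.05. All 3 groups share 1 estimate of the spread because 3 arrays estimate it poorly. For Taf4b an exact two-sided permutation test of the group means was added. Gene lists were tested with camera in limma at a preset correlation of 0.01, 1 probe set per gene (highest mean), with adjustment over 23 lists in each comparison. The lists were oocyte maternal-effect and growth, oocyte transcription factors and early germ cell genes, granulosa, theca and steroidogenesis, hedgehog, cell cycle, meiosis, gonadotropin and ovulation response, apoptosis and atresia, cholesterol synthesis and uptake, TFIID and TBP-related, immediate early and heat shock, and markers of macrophages, lymphocytes, endothelium, smooth muscle and pericytes, fibroblast stroma, ovarian surface epithelium, oviduct, adipocytes, erythroid cells and platelets, skeletal muscle, and Sertoli and male gonad. Estimated correlation and fry served as alternatives. A change of a list is the median log2 change of its members.

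The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Taf4b and, for each pair of genotypes, up to 12 called genes with the largest rise and 12 with the largest fall among probe sets with 1 symbol whose arrays do not overlap, leaving out predicted genes and clones. Where fewer than 5 were called, the 5 with the smallest p are given as not called, predicted genes included, as they are against the midpoint, and up to 4 members with the smallest p come from each list. Other genes are said to have been chosen after their values were seen.

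The procedure was tested on simulated data with the real means and spreads, with 200 of 25100 probe sets changed in each of 5 simulations. For labelled knockout against wild type it recovered 73.1% of changes of 1.5-fold, 93.1% of 2-fold and 97.6% of 3-fold, with 4.66% false among the calls. For heterozygote against wild type these shares were 68.7%, 87.8% and 99.1% with 5.65% false, and for labelled knockout against heterozygote 72.5%, 90.4% and 97.3% with 4.93% false. A list shifted by 0.3 on the log2 scale was called by camera in 5 of 5 simulations, with 0 calls of other lists. Genes were simulated independently there, so this does not cover lists whose genes vary together; other splits of the real arrays gave up to 11 list calls.

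Alternatives were a filter on the 40% dimmest probe sets, quantile normalization or subtraction of array medians on top of the deposited values, eBayes with trend and robust settings, array weights, all probe sets, a replicate block, a fold minimum of 1.5, an adjusted p of 0.1, a fit of only the groups compared, an ordinary equal-variance test, the authors' p-values, and leaving out each array. A setting without knockout 2 and heterozygote 1 was added after seeing the data. Scan dates or other batches are not given in the sources used here, and no batch could be tested. For microarrays the number of arrays limits the precision of each value.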

Results

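Transcript levels were measured in whole ovaries of 9 mice aged 3 weeks, with 3 wild-type mice, 3 mice heterozygous for a targeted Taf4b allele and 3 mice labelled as Taf4b knockouts. Taf4b encodes a gonad-enriched subunit of TFIID, the general transcription factor that binds core promoters. Each mouse gave 1 GeneChip Mouse Gene 1.0 ST array, so the spread within a genotype is a spread between mice. The deposited signals covered 28266 probe sets, of which 25100 had a gene symbol and were tested. Median intensities lay between 123.70 and 126.89 on the 9 arrays, and the number of arrays limits the precision. Pearson correlations across probe sets were between 0.989 and 0.992 between heterozygote 1 and the others, and up to 0.998 among those others. The design asks how loss of 1 or both Taf4b copies changes the ovarian transcriptome, and 3 comparisons between genotypes follow from it, with 1 more of the heterozygote against the midpoint of the other genotypes.

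Taf4b itself was measured by 1 probe set (10454077), and its level did not separate the genotypes. The mean intensity was 617 ± 116 in wild type, 542 ± 75 in heterozygotes and 453 ± 153 in the arrays labelled knockout (SD, n = 3 mice each). Knockouts 1 and 3 had the lowest Taf4b intensities of the series, 332 and 403. The array labelled knockout 2 read 626, which is 101% of the wild-type mean, so Taf4b goes against the label of this array. On the log2 scale the arrays labelled knockout differed from wild type by -0.48 ± 0.23 (SE; exact permutation p = 0.2, two-sided, n = 3), heterozygotes from wild type by -0.18 (exact p = 0.4) and labelled knockouts from heterozygotes by -0.30 (exact p = 0.4). The smallest p that 3 against 3 arrays allow is 0.1, and limma gave adjusted p = 0.514 for the first of these differences. A probe set outside the deleted part of the gene would check nothing, and where this probe set lies relative to the deletion is not given in the sources used here. Directions below that involve the arrays labelled knockout are drawn with this array among them unless the text says without knockout 2.

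**Figure D1:**
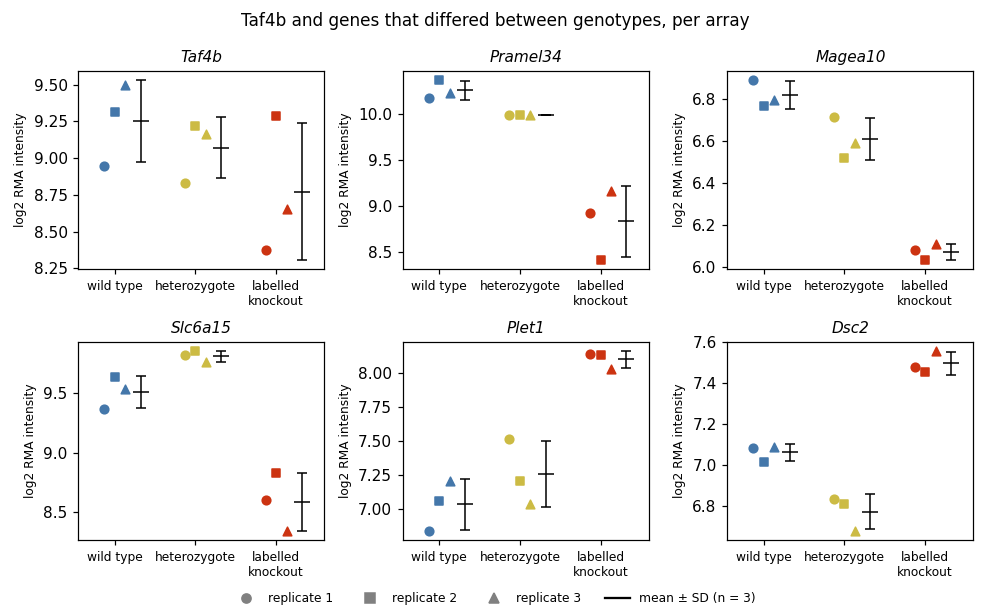
Log2 RMA intensity of Taf4b and of 5 genes that differed between genotypes, 1 point per array with the mean and SD of each group of 3 beside the points. Taf4b in the array labelled knockout 2 sits at 9.29, among the wild-type arrays, while Pramel34 in the same array sits at 8.41, below all wild-type arrays.

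Between the arrays labelled knockout and wild type, 9 genes named by the rule fell and 3 rose. Pramel34, a member of the multicopy PRAME-like family, fell by 1.42 on the log2 scale (SE 0.16, adjusted p = 0.0279, limma), from an intensity of 1224 ± 87.8 to 467 ± 118 (SD, n = 3). The X-linked genes Magea10, a melanoma antigen family member, and Xlr5b and Xlr5a, of the X-linked lymphocyte-regulated family, fell by 0.74, 0.94 and 0.83 (SE 0.06, 0.11 and 0.10). Slc6a15, a transporter of neutral amino acids, fell by 0.93 (SE 0.12, adjusted p = 0.0423, limma), and Slc15a5, of the peptide transporter family, by 0.65 (SE 0.06, adjusted p = 0.0084, limma). The zinc finger gene Zfp735 fell by 1.00 (SE 0.11), Trpc6, a receptor-operated cation channel, by 0.61 (SE 0.06), and Nova1, a regulator of splicing in neurons, by 0.55 (SE 0.06). Nova1 has 2 probe sets, and only the called probe set is given. Plet1, a surface glycoprotein of placental and epithelial progenitor cells, rose by 1.07 (SE 0.13, adjusted p = 0.0363, limma), from 132 ± 16.9 to 275 ± 11.8 (SD, n = 3). Hsd17b11, a hydroxysteroid dehydrogenase of lipid droplets, rose by 0.53 (SE 0.07), and Tapbp, which loads peptides onto class I major histocompatibility molecules, by 0.38 (SE 0.05). Pramel34, Plet1, Zfp735 and Slc15a5 carry the older symbols C87414, 1600029D21Rik, 1700012C15Rik and 9830102E05Rik in the deposited annotation.

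In total 19 probe sets of 15 genes passed an adjusted p of 0.05 in this comparison, 3 higher and 16 lower, and at all 19 the 3 arrays labelled knockout lay on 1 side of the 3 wild-type arrays. Across all tested probe sets such a separation was seen for 14.3%, where chance gives 10%. Outside the rule for named genes, and chosen after their values were seen, were AA792892 at -1.44 (adjusted p = 0.0029, limma), E330014E10Rik between -1.41 and -1.44 at its called probe sets and OTTMUSG00000010333 at -0.89. Not all of the 5 probe sets of E330014E10Rik were called. Together with Pramel34, AA792892 and E330014E10Rik gave 7 of the called probe sets, whose values correlated at 0.989 or above across the 9 arrays, so these near-identical copies are reported as uncertain and may not be separate events. The count of 19 fell to 2 without knockout 1 or without wild type 2, to 4 without heterozygote 2 or heterozygote 3, to 6 without wild type 1, to 7 without wild type 3 and to 8 without heterozygote 1. It was 19 without knockout 3 and 20 without knockout 2, with 13 shared each time. Of the 3 higher calls, 0 were left without knockout 1, knockout 3, wild type 2, heterozygote 2 or heterozygote 3. Without knockout 2, Plet1, Hsd17b11, Tapbp, Zfp735 and Xlr5a were not called. When only the 6 arrays compared were fitted, 0 passed in limma, an ordinary equal-variance test on log2 values gave 4, and 2675 probe sets, 1227 higher and 1448 lower, had an unadjusted p under 0.05 with all arrays.

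**Figure D2:**
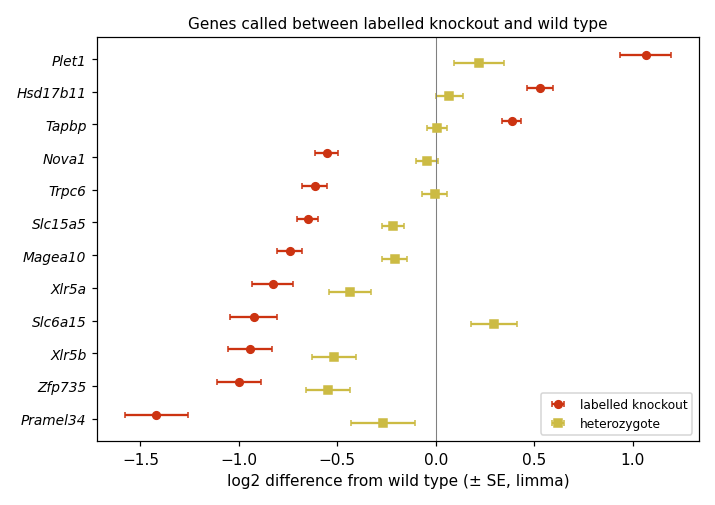
Log2 difference from wild type, with the limma SE, for the arrays labelled knockout (circles) and heterozygotes (squares) at the 12 named genes called between labelled knockout and wild type. Heterozygote differences run from -0.55 for Zfp735 to 0.30 for Slc6a15, and none of them passed the test.

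Genes of the dividing cell fell as a group in the arrays labelled knockout. All 30 members of the cell cycle list lay below wild type, with a median change of -0.22 (adjusted p = 1.04e-16, camera), and adjusted p = 0.0887 with an estimated correlation. Mcm5 and Mcm2, subunits of the replicative helicase, stood at -0.36 and -0.26, the mitotic kinase Plk1 at -0.31 and the chromosomal passenger gene Birc5 at -0.36. None of the 30 passed over all genes tested, and 11 fell when adjusted over the list alone. The theca and steroidogenesis list rose, with 19 of 20 members above wild type and a median of 0.34 (adjusted p = 2.44e-09, camera; adjusted p = 0.0887 with an estimated correlation). Its members included the prolactin receptor gene Prlr at 0.42, the retinaldehyde dehydrogenase gene Aldh1a1 at 0.36, the steroidogenic regulator Nr5a1 at 0.27 and the angiotensin receptor gene Agtr2 at 0.41. Knockout 2 had the highest score for this list, 0.51 against 0.11 and 0.02 in knockouts 1 and 3, and the median was 0.26 without it. Of these 20 genes 0 passed over all genes tested and 7 rose when adjusted over the list alone.

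Oocyte genes were lower on average in the arrays labelled knockout, but through knockout 2. The oocyte maternal-effect and growth list fell, with 32 of 39 members below wild type and a median of -0.22 (adjusted p = 1.11e-06, camera; adjusted p = 0.573 with an estimated correlation). Oog3, an oogenesin, stood at -0.41, Omt2b at -0.48, Obox5, an oocyte homeobox gene, at -0.66 and the cell cycle transcription factor gene E2f8 at -0.34; 1 gene fell when adjusted over the list alone and 0 over all genes tested. The list of oocyte transcription factors and early germ cell genes fell, with 18 of 24 below wild type and a median of -0.18 (adjusted p = 0.0044, camera; adjusted p = 0.599 with an estimated correlation), and 2 genes fell when adjusted over the list alone (0 over all genes tested). Ddx25, a germ cell RNA helicase, stood at -0.37 and Tdrd9, of the piRNA pathway, at -0.49. Without knockout 2 the medians were -0.03 and 0.0022 and neither list passed. The transcription factor list also failed to pass without wild type 1 (-0.07) and with the dimmest probe sets left out (-0.17); it stood at -0.28 without knockout 3 and -0.30 without wild type 3. The mean deviation of the maternal list was -0.39 in knockout 2, 0.12 in knockout 1 and 0.18 in knockout 3, against 0.33, 0.23 and -0.01 in the wild-type arrays. The meiosis list fell, with 17 of 22 below and a median of -0.17 (adjusted p = 0.0027, camera; adjusted p = 0.360 with an estimated correlation). The synaptonemal complex gene Sycp3 stood at -0.91 and the meiotic cohesin gene Smc1b at -0.78, with 0 genes passing when adjusted over the list alone or over all genes tested, and the list did not pass without wild type 1 (median -0.14) or with the dimmest probe sets left out (-0.04).

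Granulosa genes did not pass as a list (median -0.08, 20 of 30 below wild type, adjusted p = 0.0732, camera), and 0 passed when adjusted over the list alone or over all genes tested. The activin-binding protein gene Fst stood at -0.72, the follicle-stimulating hormone receptor gene Fshr at -0.79 and the inhibin beta subunit gene Inhbb at -0.84. The TFIID and TBP-related list, to which Taf4b belongs, fell by a median of 0.07 on the log2 scale (median -0.07, 18 of 26 below, adjusted p = 0.0301, camera; adjusted p = 0.142 with an estimated correlation), with Taf9b at -0.42 and Taf3 at -0.20. It did not pass without knockout 1 (-0.04), without wild type 3 (-0.05) or with the dimmest probe sets left out (-0.06), and was -0.04 without wild type 2. Cholesterol synthesis and uptake rose, with 19 of 24 above and a median of 0.07 (adjusted p = 0.0151, camera; adjusted p = 0.599 with an estimated correlation), led by Hmgcs1 at 0.29, and did not pass without knockout 2 (0.01) or without wild type 1 (0.08), and was 0.16 without knockout 3. In neither of these lists did a gene pass when adjusted over the list alone or over all genes tested. The hedgehog (adjusted p = 0.590), gonadotropin and ovulation response (0.587), apoptosis and atresia (0.599) and immediate early and heat shock lists (0.587) did not pass in camera, although Igfbp5, an insulin-like growth factor binding protein in the apoptosis list, stood at 0.58 (adjusted p = 0.0049 over the list alone, limma).

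Markers of non-follicular cells rose in the arrays labelled knockout beside these gene groups. The ovarian surface epithelium list rose, with 13 of 16 above wild type and a median of 0.43 (adjusted p = 1.57e-10, camera; adjusted p = 0.0887 with an estimated correlation); mesothelin (Msln) stood at 0.46, the uroplakin gene Upk1b at 0.78, Aldh1a2 at 0.65 and the keratin gene Krt19 at 0.67. All 22 macrophage and antigen presentation genes lay above wild type, with a median of 0.40 (adjusted p = 1.49e-13, camera; adjusted p = 0.165 with an estimated correlation), among them the lysozyme gene Lyz2 at 0.97, Adgre1 at 0.46, the complement gene C1qa at 0.39 and Cd68 at 0.61. The mean deviation of the macrophage list was 0.36 in knockout 1, 0.01 in knockout 2 and 0.54 in knockout 3. It was -0.04, -0.15 and -0.13 in the wild-type arrays, so the rise came mostly from knockouts 1 and 3. The macrophage median was 0.26 without knockout 3 and 0.53 without knockout 2. Adjusted over the list alone, 12 surface epithelium and 9 macrophage genes rose, and 0 over all genes tested. Fibroblast stroma (median 0.22, adjusted p = 1.77e-05, camera; adjusted p = 0.0887 with an estimated correlation) and endothelial markers (median 0.15, adjusted p = 9.76e-06, camera; adjusted p = 0.0887 with an estimated correlation) rose, with Lum, a collagen-binding proteoglycan, at 0.59 and the endothelial adhesion gene Esam at 0.32. Each of these lists had 1 gene that rose when adjusted over the list alone and 0 over all genes tested.

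Markers of tissue next to the ovary moved with them. The adipocyte list rose, with 14 of 16 above wild type and a median of 0.15 (adjusted p = 0.0012, camera; adjusted p = 0.360 with an estimated correlation). That median was 0.05 without knockout 1 and 0.26 without wild type 1. The oviduct list rose by a median of 0.10 (adjusted p = 0.0261, camera; adjusted p = 0.390 with an estimated correlation), with the oviduct glycoprotein gene Ovgp1 at 2.03 (SE 0.53) and Tppp3 at 0.42, and did not pass without knockout 3 (0.03), without wild type 3 (0.04) or with the dimmest probe sets left out (0.07). Adjusted over the list alone 2 oviduct and 0 adipocyte genes rose, and 0 over all genes tested. The lymphocyte (adjusted p = 0.748), smooth muscle and pericyte (0.0557), erythroid and platelet (0.587), skeletal muscle (0.953) and Sertoli and male gonad lists (0.334) did not pass in camera; the B cell gene Ms4a1 stood at -0.84 (adjusted p = 0.0014 over the list alone, limma). No list call in any comparison held with an estimated correlation, while fry called 6 lists here. Fry asks whether the genes of a list differ on average between the groups, without comparing them with genes outside the list. The median and the direction of the test differed in sign for the hedgehog, apoptosis and skeletal muscle lists.

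**Figure D3:**
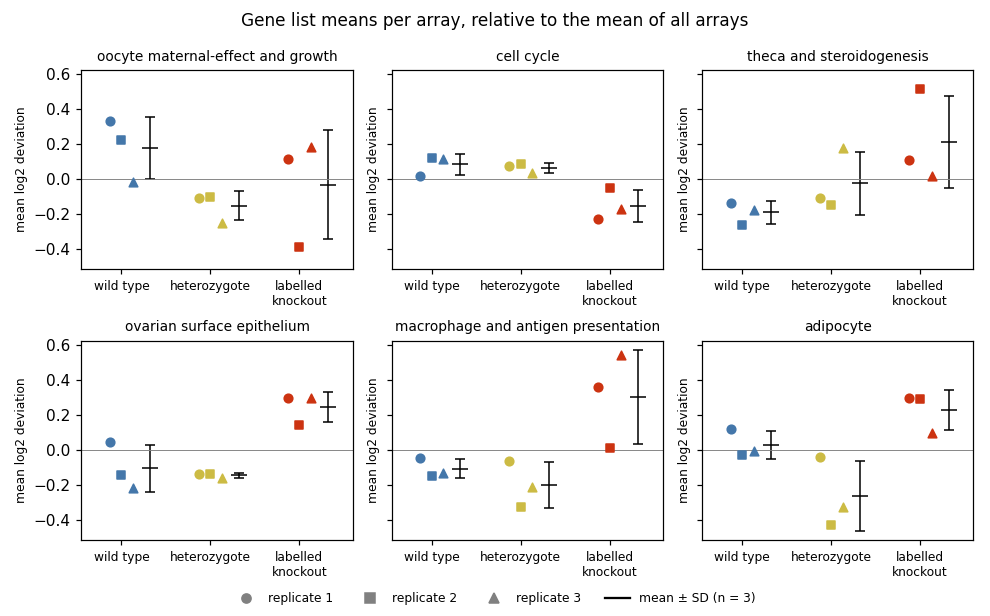
Mean log2 deviation of the members of 6 gene lists from the mean of all 9 arrays, 1 point per array with the mean and SD of each group of 3. The oocyte list runs from -0.39 in knockout 2 to 0.33 in wild type 1, and the 3 arrays labelled knockout lie below all others for the cell cycle list.

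Between heterozygotes and wild type, oocyte genes were lower as a group in camera at the preset correlation, while no single gene passed. All 39 measured genes of the oocyte maternal-effect and growth list lay below wild type (median -0.32, adjusted p = 3.52e-19, camera), with adjusted p = 0.310 with an estimated correlation. Oog3 stood at -0.32, Oog4 at -0.40, the oocyte gene Oas1d at -0.42 and Gpr3, a receptor that keeps oocytes arrested in meiosis, at -0.27. The oocyte transcription factor and early germ cell list fell, with 23 of 24 below and a median of -0.31 (adjusted p = 2.87e-09, camera; adjusted p = 0.310 with an estimated correlation), including Nobox, a homeobox regulator of early folliculogenesis, at -0.53, the piRNA gene Mael at -0.65, Ddx25 at -0.38 and the oocyte growth factor gene Bmp15 at -0.32. Adjusted over the list alone, 0 genes of the first list and 1 of the second fell, and 0 over all genes tested. Without wild type 1 the median of the second list was -0.20.

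The adipocyte list fell in heterozygotes, with 12 of 16 below wild type (median -0.19, adjusted p = 7.74e-04, camera; adjusted p = 0.310 with an estimated correlation); Car3, an abundant carbonic anhydrase of fat, stood at -0.87, the adiponectin gene Adipoq at -0.78 and the adipsin gene Cfd at -1.18. Adjusted over the list alone these 3 genes fell, and 0 over all genes tested. Hedgehog pathway genes fell (median -0.18, 9 of 13 below, adjusted p = 0.0042, camera; adjusted p = 0.242 with an estimated correlation), with the transcription factor gene Gli3 at -0.35 and the receptor gene Ptch1 at -0.26. Fibroblast stroma (median -0.13, adjusted p = 0.0022, camera; adjusted p = 0.242 with an estimated correlation), TFIID (-0.07, adjusted p = 0.0042; adjusted p = 0.231 with an estimated correlation) and endothelial genes (-0.09, adjusted p = 0.0082; adjusted p = 0.310 with an estimated correlation) fell, and cholesterol synthesis rose (0.08, adjusted p = 0.0082; adjusted p = 0.710 with an estimated correlation). In these 5 lists 1 gene, Col6a3 at -0.32, passed when adjusted over the list alone, and 0 over all genes tested. The endothelial call was lost without wild type 1 (-0.05), heterozygote 2 (-0.11) or heterozygote 3 (-0.06), and the cholesterol call without heterozygote 2 (0.05). Quantile normalization ended the TFIID (-0.03) and endothelial calls (-0.06), as did leaving out the dimmest probe sets (-0.04 and -0.09), and the TFIID call was lost without knockout 2 and heterozygote 1 (-0.06). Without wild type 1 the medians of hedgehog, fibroblast and adipocyte genes were -0.12, -0.06 and -0.12, and that of adipocyte genes was -0.29 without wild type 2 and -0.36 with the dimmest probe sets left out.

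In limma 0 of 25100 probe sets were called in heterozygotes against wild type (smallest adjusted p = 0.815), with 1443 at an unadjusted p under 0.05 where chance gives 1255. An ordinary equal-variance test and the authors' deposited p-values after Benjamini-Hochberg adjustment also gave 0. The 5 smallest p-values, none of them called, belonged to the trace amine receptor gene Taar6 at 0.35, the predicted gene LOC665703 at -0.34, Ttc6 at -0.32, the olfactory receptor gene Olfr446 at 0.34 and the formyl peptide receptor gene Fpr3 at 0.31, all with mean intensities below 40 in wild type. Fry called 0 lists in this comparison.

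Between the arrays labelled knockout and heterozygotes, Dsc2, a desmosomal cadherin, rose by 0.72 (SE 0.06, adjusted p = 0.0109, limma), from an intensity of 109 ± 6.31 to 180 ± 6.96 (SD, n = 3). Slc6a15 fell by 1.22 (SE 0.12, adjusted p = 0.0207, limma), Trpc6 by 0.61 (SE 0.06, adjusted p = 0.0317, limma) and Nova1, at the same probe set as above, by 0.51 (SE 0.06, adjusted p = 0.0400, limma). AA792892, named after its values were seen, fell by 1.17 (adjusted p = 0.0109, limma). In the gene order of the mouse RefSeq table, Dsc2 lies 7 measured genes from Taf4b. At all 6 called probe sets (1 higher, 5 lower, 5 genes) the arrays of the 2 genotypes did not overlap, as at 16.2% of all probe sets, where chance gives 10%. All 5 falling probe sets were also called against wild type in the same direction, where independent calls would share 0.0045. Both comparisons use the same labelled knockout arrays, which by itself raises the overlap. The covariance of the log2 changes was 0.0188, against a mean of 0.0084 simulated with no effect. Genes were simulated independently there, so the simulation does not cover genes that vary together and cannot show a shared effect.

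Macrophage, surface epithelium, fibroblast, endothelial and adipocyte markers rose in the arrays labelled knockout against heterozygotes as well. The lymphocyte (median 0.01, adjusted p = 0.674, camera) and smooth muscle and pericyte lists (0.09, adjusted p = 0.0663) did not pass. All 22 macrophage genes (median 0.51, adjusted p = 1.66e-14, camera; adjusted p = 0.165 with an estimated correlation) and all 16 surface epithelium genes (median 0.36, adjusted p = 8.30e-12, camera; adjusted p = 0.115 with an estimated correlation) lay above the heterozygote mean. Lyz2 stood at 1.01, the complement gene C1qb at 0.68, Aldh1a2 at 0.75 and Wt1 at 0.38. Fibroblast stroma (0.33, adjusted p = 2.63e-09, camera; adjusted p = 0.0519 with an estimated correlation), endothelial (0.24, adjusted p = 3.87e-09; adjusted p = 0.0556 with an estimated correlation) and adipocyte genes (0.30, adjusted p = 1.10e-07; adjusted p = 0.164 with an estimated correlation) rose, with Col6a3 at 0.51, Kdr at 0.41, Car3 at 1.55 and Adipoq at 1.10. Adjusted over the list alone, 15 macrophage, 12 surface epithelium, 12 fibroblast, 4 endothelial and 8 adipocyte genes rose, 1 fibroblast gene fell, and 0 passed over all genes tested. The adipocyte median was 0.67 with the dimmest probe sets left out.

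The cell cycle list fell again, with all 30 members below heterozygotes (median -0.22, adjusted p = 6.42e-12, camera; adjusted p = 0.164 with an estimated correlation), Mcm5 at -0.28 and the cyclin gene Ccnb2 at -0.38, and 8 genes falling when adjusted over the list alone (0 over all genes tested). Theca and steroidogenesis rose (0.21, adjusted p = 1.73e-05, camera; adjusted p = 0.173 with an estimated correlation), with Prlr at 0.46 and 3 genes rising when adjusted over the list alone (0 over all genes tested). That median was 0.13 without knockout 2, 0.36 without knockout 3, 0.32 without heterozygote 3, and 0.09 with the call lost without both knockout 2 and heterozygote 1. Oocyte maternal-effect genes rose by a median of 0.11 (adjusted p = 0.0231, camera; adjusted p = 0.768 with an estimated correlation), and oviduct genes by 0.13 (adjusted p = 0.0444, camera; adjusted p = 0.461 with an estimated correlation). The oocyte call was lost without knockout 1 (0.04), knockout 3 (0.03) or heterozygote 3 (0.10) and with quantile normalization (0.10) or the dimmest probe sets left out (0.11), and its median was 0.30 without knockout 2. The oviduct call was lost without knockout 1 (0.04), knockout 3 (0.08), heterozygote 2 (0.13) or heterozygote 3 (0.10) and with the dimmest probe sets left out (0.16), and its median was 0.22 without knockout 2 and heterozygote 1. Of the called probe sets, limma kept 0 without knockout 1, heterozygote 2 or heterozygote 3, and 3 without knockout 3, wild type 2, wild type 3 or heterozygote 1 (which gave 6 calls, 4 higher and 2 lower). At an unadjusted p under 0.05 there were 3584, 1936 higher and 1648 lower, and an ordinary equal-variance test called 1. Without knockout 2 the count rose to 261, with 183 higher and 78 lower. These are probe sets, and a count of genes is not given here. Hmcn1, with 77 tested probe sets, was among the higher ones repeatedly, so fewer genes were called.

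Against the midpoint of wild type and labelled knockout, no gene of the heterozygote passed in limma (0 of 25100, smallest adjusted p = 0.133, 2505 at an unadjusted p under 0.05; no other tool was run). Dsc2 came closest at -0.51 (SE 0.05), followed at adjusted p = 0.457 (limma) by Slc6a15 at 0.76, Car3 at -1.21, the T cell gene Cd3d at 0.34 and Olfr446 at 0.37. Without heterozygote 1 the count was 1, Adipoq at -1.23. As groups, macrophage (median -0.32, adjusted p = 1.10e-09, camera), fibroblast stroma (-0.22, adjusted p = 4.01e-08) and oocyte maternal-effect genes (-0.22, adjusted p = 1.41e-09) lay below the midpoint, with adjusted p = 0.270, 0.0717 and 0.439 with an estimated correlation. Camera placed 9 of the 23 lists away from the midpoint, 1 higher and 8 lower, and fry 2.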

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

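Of the tests in this part, the one on genomic DNA or unspliced RNA was chosen after the result was seen. Probe sets without a gene symbol, which the comparisons leave out, were searched for signal at least 3-fold above the highest wild-type array. Heterozygote 1 had 115 of 3166, knockout 3 had 1, and the other 4 arrays labelled heterozygote or knockout had 0. The one in knockout 3 is described as an antibody light chain and read 75.6 against 18.2. Of the 115, 87 are described as small nucleolar RNAs of chromosome 7 between 66603051 and 67042140 (NCBIM37); they repeat 33 distinct sets of values. Their intensities in heterozygote 1 were between 24.5 and 237 with a median of 133, while the other 8 arrays stayed between 5.48 and 21.6 with a median of 7.48. Mitochondrial transfer RNA probe sets were also among the 115, at up to 716 against 68.9.

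Heterozygote 1 also stands apart in the named genes, with correlations of 0.989 to 0.992 to the other arrays and 33.6% of the variance on a first component that separates it. Olfactory, vomeronasal and trace amine receptor genes, which an ovary should hardly transcribe, deviated in it by a median of 0.13 on the log2 scale from the mean of the other arrays, with 77.2% of 1429 above 0, against medians between -0.03 and -9.95e-05 in the other 8, so genomic DNA or unspliced RNA in this library may be part of the difference. Raised signal without a gene symbol was not confined to this array. A probe set of chromosome 2, chosen after its values were seen, read 11387 in heterozygote 1 and 7084 in wild type 3. It read between 1822 and 3292 in knockout 2, wild type 2 and heterozygotes 2 and 3. In wild type 1, knockout 3 and knockout 1 it read 253, 60.9 and 58.3. A probe set of chromosome 9, chosen likewise, read 9.67 in wild type 1, 10.9 in knockout 1 and 24.4 in knockout 3, against 84.8 or more in the others. A second component of the named genes, with 23.6% of the variance, cut across the genotypes. Knockouts 1 and 3 stood at 16.7 and 16.8 on it, wild type 1 at 8.83 and heterozygote 1 at 8.04. The other arrays stood between -18.9 and -3.37. Heterozygote 1, on the side of knockouts 1 and 3 there, read highest at the chromosome 2 probe set. A difference between libraries that sets apart knockouts 1 and 3, and wild type 1 with them, is not ruled out. Neural tissue is argued against, since 16 marker genes had a median deviation of -0.0015 with a 75th percentile of 0.05. A compressed signal range cannot be told apart from a true rise of receptor signal: against other genes of the same level the receptors were higher by 0.0796 (95% bootstrap interval 0.0640 to 0.0953), which lies between the bounds set for either. No biological explanation for a single mouse was tested.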

How the results depend on the processing

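The setting without knockout 2 and heterozygote 1 was chosen after seeing the data; the others were planned. Called probe sets between labelled knockout and wild type (19) came to 63 with the dimmest left out, 34 with trend and robust settings, 199 with array weights (77 higher and 122 lower), 79 at an adjusted p of 0.1, 0 with the 2 groups alone, 4 by an ordinary equal-variance test, 3 from the authors' p-values, and 2 to 20 leaving out each array (20 without knockout 2, of which 13 shared). Between labelled knockout and heterozygote (6) they came to 56 (27 higher and 29 lower), 29, 152 (92 higher and 60 lower), 57, 0, 1 and 1 under those settings, to 11 with quantile normalization, 12 with array medians subtracted (3 higher and 9 lower, against 1 and 5), and 0 to 261 leaving out each array. Without both arrays in doubt the counts were 30 and 409, with 16 and 6 shared. With fewer probe sets tested or fewer arrays fitted the adjustment or the degrees of freedom change by construction; for the others the cause was not tested. Against the midpoint the count was 0 to 1 leaving out each array (Adipoq without heterozygote 1) and 4 without both arrays in doubt (Adipoq, H2-Ab1, Cd74 and Cyp2e1, all lower), and 0 otherwise; heterozygote against wild type gave 0 under all alternatives, with limma's unadjusted p under 0.05 for 911 to 1878 probe sets leaving out 1 array. No clear pairing of the mice by the numbers 1 to 3 was seen. Deviations of same-numbered arrays correlated between -0.19 and 0.33, and 2 of 9 pairs were above 0.1. Those of arrays with different numbers correlated between -0.37 and 0.26, and 4 of 18 pairs were above 0.1. The difference was not tested, and a pairing cannot be excluded. With the replicate block the pairing left 3 calls against wild type (AA792892, with 2 probe sets, and Magea10) and 0 against heterozygote, and the list tests called 32.

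Of 69 list tests 30 were called, 0 with an estimated correlation, 13 by fry, and 27 to 36 leaving out each array. The oocyte transcription factor list between labelled knockout and wild type turned from -0.18 to 0.0022 without knockout 2, alone or with heterozygote 1 (-0.2978 to 0.0022 leaving out each array), and the cause was not tested. Across lists and alternatives 1046 results kept their outcome, 43 passed in addition and 82 no longer passed. A further 2 changed sign where the main result or the alternative passed. The 1046 include any change of sign where neither passed, so changes of direction were not counted in full. The 16 called results of named genes kept their direction in all alternatives run. By the rule for named genes their arrays do not overlap, so leaving out an array could not turn the direction, and this lends them no support. Of 240 such results under the alternatives, 117 stayed past the threshold and 123 did not. Magea10 ranged from adjusted p = 0.0037 to 0.0857 (limma) and Plet1 from 0.0185 to 0.210. Taf4b stayed on the same side in all alternatives, between -0.74 and -0.28 against wild type, adjusted p between 0.122 and 0.848 (limma). The median change of all genes between labelled knockout and heterozygote was -0.0127 as deposited and -0.0450 after subtraction of array medians. Signal over background limits the dim probe sets.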

Other observations

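Of the tests in this part, those of a wrong label for knockout 2, of dilution by tissue from outside the ovary, of strain variants between labelled knockout and heterozygote and of the PRAME family were chosen after the result was seen. Without knockout 2, the comparison of labelled knockout with heterozygote named 261 probe sets, and granulosa genes were among them: 6 of 30 were lower and 0 higher. With all arrays the granulosa list did not pass there (median -0.06, 18 of 30 below, adjusted p = 0.367, camera). Fst, whose protein binds activin, fell by 1.03 (SE 0.12, adjusted p = 0.0254, limma). In the same comparison 6 of 22 macrophage genes were higher, and Ctss, a lysosomal protease of antigen-presenting cells, rose by 1.40 (SE 0.17, adjusted p = 0.0308, limma). Against wild type the same setting added Obox7, an oocyte homeobox gene, at -0.81 (adjusted p = 0.0221, limma), and Fbxo47, the 1 higher call, at 0.52 (adjusted p = 0.0435, limma), while Plet1, Hsd17b11, Tapbp, Zfp735 and Xlr5a were no longer called. These genes were chosen after their values were seen. Taf4b in the remaining knockouts 1 and 3 was 53.8% and 65.3% of the wild-type mean, against 73.8% in heterozygote 1 and 80.0% in wild type 1. The chromosome 2 probe set above was also low in knockouts 1 and 3 and in wild type 1. A difference between libraries is therefore not ruled out as a source of these calls.

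PRAME-like genes and the desmosomal cadherins near Taf4b had uneven values around the called ones. Dsg2, a desmosomal cadherin gene 14 measured genes from Taf4b, stood at 0.35 against wild type and 0.47 against heterozygote, beside Dsc2 at 0.43 and 0.72. In the same order Dsg1b stood at 0.37 and 0.11, Dsc3 at 0.19 and 0.09, Dsg1c at 0.05 and -0.03, Dsc1 at 0.02 and 0.00, Dsg4 at 0.00 and -0.12, Dsg3 at -0.10 and 0.03 and Dsg1a at -0.16 and -0.05. PRAME-like genes outside the calls went both ways against wild type, from Pramel27 at -0.65 and Pramel15 at -0.63 to Pramel31 at 1.10 and Pramel17 at 0.44. Of these 18 genes 13 were lower. The 18 had a median of -0.0514, at the 6.74th percentile of 10000 random sets of the same level. The random sets were matched on level alone and do not cover genes that vary together. Of the 100 named genes nearest to Taf4b, 7% had an unadjusted p under 0.05 between labelled knockout and wild type, against 11.7% of other genes (one-sided Fisher's exact p = 0.955). Between labelled knockout and heterozygote the shares were 19% and 15.2% (one-sided Fisher's exact p = 0.176). Strain variants around the targeted allele cannot be told apart from other causes here: the first share is lower than elsewhere, but 5 of its 7 genes, Dsc3, Dsc2, Dsg2, B4galt6 and Mep1b, lie between 6 and 20 measured genes on 1 side of Taf4b, and a share over 100 genes would miss variants acting on so few.

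Knockout 2 has wild-type Taf4b intensity, and the other genes leave its label open. Over 19 distinct probe sets called without it, where wild type is 0 and the mean of knockouts 1 and 3 is 1, its median position was 1.27 with a lower quartile of 0.755, and 15 of 19 were above 0.5, while heterozygote arrays had medians between 0.203 and 0.245. Without the 7 PRAME-type probe sets its median was 0.963, with a lower quartile of 0.214 and 8 of 12 above 0.5. Heterozygotes 1, 2 and 3 had 1, 2 and 4 of 12 above 0.5. Their levels did not serve to choose these probe sets, but their spread entered the shared estimate. However, 259 probe sets that set knockouts 1 and 3 apart from heterozygotes placed knockout 2 at 0.330, within the wild-type arrays' 0.188 to 0.399. These sets of probe sets go different ways, so a wrong label cannot be told apart from a true knockout here. Knockout 2 also had the lowest oocyte score (-0.39) and correlated best with heterozygote 3 (0.996). Transcript from the targeted allele may give the Taf4b signal and cannot be told apart from other sources here, because only 1 probe set measures the gene; differences in ovarian state between mice were not tested.

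Less cell cycle signal and more surface epithelium and macrophage signal in the arrays labelled knockout could come from the mix of cells in the sample. Tissue from outside the ovary that did no more than dilute ovarian RNA would lower theca genes too. The lower quartile of the theca and steroidogenesis list was instead 0.17 above wild type, and 0.15 without knockout 2. Dilution beside a separate rise of theca genes is not excluded by this, and the cell cycle (median -0.22) and meiosis lists (-0.17) fell. Oviduct or fat taken along cannot be told apart from a change within the ovary: with the adipocyte and oviduct scores as covariates, the macrophage median kept 19.8% of its size (0.08 from 0.40), the surface epithelium list 64.3% (0.28 from 0.43) and the cell cycle list 86.4% (-0.19 from -0.22), with 4 residual degrees of freedom. A change in ovarian cell types or in follicle number with the genotype is a possible biological explanation, and it was not tested.

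With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split called 19 probe sets between labelled knockout and wild type (1 split as large, highest other 0), 0 between heterozygote and wild type (10 as large, highest other 0) and 6 between labelled knockout and heterozygote (1 as large, highest other 0). For lists, the real splits called 13 (1 as large, highest other 9), 8 (2 as large, highest other 10) and 9 (3 as large, highest other 11). Against the midpoint the real grouping gave 0 calls, so all 100 regroupings drawn gave as many and the comparison says nothing about chance; 98 gave 0, 1 gave 335 with knockout 1, knockout 3 and wild type 1 as the set placed against the midpoint, and 1 gave 38 with the 3 arrays labelled knockout as the set.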
